A study of Mus musculus with 6 samples.

How the data were processed

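The series holds 6 bulk RNA sequencing libraries of mouse paraventricular thalamus, 3 after chronic constriction injury (CCI, replicates 1 to 3) and 3 untreated wild-type controls (replicates 4 to 6). Per the submitters' processing notes, poly-A selected RNA was reverse transcribed from random primers and sequenced on a NovaSeq instrument, and the notes name fastp 0.22.0, HISAT2 2.1.0, HTSeq 0.9.1, DESeq 1.38.3, StringTie 2.2.1 and the GRCm39 assembly. No strand setting is stated. The deposited table gives, per the file headers, a read count and an FPKM value for each library and gene, and a Length for each gene in bp. The counts are whole numbers and were used as deposited. The deposited FPKM was checked to equal the count divided by Length and by the column total. Reads were not analysed here.

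Of the genes of the table, 4001 have no count and 51 no symbol. Groups were taken from the labels. Coding length and GC content came from GENCODE M21, which is on GRCm38 whereas the table is on GRCm39, so it was used by Ensembl identifier alone, for 21805 genes of the table and 14220 of the 14259 tested (99.7%).

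Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and the quasi-likelihood F-test, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Levels are CPM (counts scaled to the TMM-adjusted library total). The standard error is the log2 fold change divided by the root of F. TMM factors were 1.21 to 1.25 in CCI and 0.69 to 0.90 in control. Fixed lists of genes were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry. Counts adjusted over the list alone used the p-values of its members. DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were also used. Intervals on count ratios are 95% and cover counting error alone.

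The comparison, the 37 lists, the scaling, filter, test and leave-one-out alternatives and the naming rule were fixed before the data were examined. The naming rule took the 10 largest rises and 10 largest falls that passed, whose 3 CCI libraries all lay on one side of the 3 control libraries. It asked for a mean of at least 1 FPKM in the higher group. Symbols of Gm and digits, ending in Rik, of BC, AC or AL accession form, and Ensembl identifiers were left out. Other accession-like symbols, such as AI593442, were kept. It then took Gfap, and up to 4 members of each list with the smallest unadjusted p. The corrections for coding length, GC content and mean expression, the thinning to equal total counts, the second marker sets and the named astrocyte markers that rose were chosen after the data were seen. Alternatives tried were DESeq2 size factors, no filter, a stricter filter, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the DESeq2 Wald test and limma-voom. The stricter filter moved the fold changes of shared genes by 0.35 at the median, and the FPKM scales by 0.51 and 0.60.

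The code was tested on simulated data of 14220 genes with 200 changed, where 37% of 2-fold and 88% of 4-fold changes were recovered with 6 false calls, and 0 genes were called with no change. With a simulated length trend there were 2947 false calls uncorrected and 11 corrected. That trend had a form that the correction can fit, so this checks the code alone. The labels do not say how mice were divided among libraries or when libraries were prepared, and a paired analysis was not possible. Some genes that met the naming rule are not reported here.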

Results

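Gene expression was measured by bulk RNA sequencing of the paraventricular thalamus, a midline thalamic nucleus, in mice with chronic constriction injury and in untreated wild-type mice. Chronic constriction injury (CCI) is a rodent model of neuropathic pain in which a peripheral nerve is loosely tied. The series title names astrocyte activation in this nucleus during lasting neuropathic pain as its subject, and the comparison of CCI with control addresses which transcripts differed between the groups. There were 3 CCI libraries (replicates 1, 2 and 3) and 3 control libraries (replicates 4, 5 and 6). The design text gives 30 mice in each group and does not say how they were divided among libraries, so p-values measure the spread between these libraries, which may be partly technical. The deposited counts summed to 7989139, 9056914 and 10529886 in CCI and to 12454029, 12337448 and 15438268 in control. Of the genes in the table, 16621 to 16959 had at least 1 count in a CCI library and 15800 to 16182 in a control library.

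In CCI, the reactive astrocyte gene Gfap and most genes of the myelin and oligodendrocyte precursor lists rose, while several GABA-A receptor subunits and heat shock genes fell. Of 14 cortical and hippocampal neuron genes 9 rose (5 without CCI replicate 3), a list call lost with an estimated correlation (adjusted p = 0.797 with an estimated correlation), and of 15 genes of the paraventricular and midline thalamus none rose. Of 14259 genes tested with edgeR's quasi-likelihood test, 7461 (52.3%) passed an adjusted p of 0.05, 3853 of them higher and 3608 lower in CCI. Changes of over 2-fold were found in 2568 of the higher and 2021 of the lower genes. In 63.0% of the tested genes the 3 CCI libraries lay entirely above or below the 3 control libraries, against 10% by chance. Leaving out 1 library gave 5474 calls (without CCI replicate 1) to 8904 (without control replicate 5). Control replicate 5 lay apart from the other controls. Its Pearson correlation on log2(FPKM + 1) was 0.973 with control replicate 4 and 0.976 with replicate 6, which correlated at 0.995 with each other. Its 50 most abundant genes took 20.7% of its counts, against 14.2% and 14.5% in replicates 4 and 6. The split of 51.6% higher among the calls depended on scaling. With limma on the deposited FPKM, as log2(FPKM + 1), 8159 genes passed and 83.2% of them were higher, because fold changes lay 0.51 (log2) higher at the median than with TMM scaling.

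Gfap (ENSMUSG00000020932), the astrocyte intermediate filament gene on chromosome 11 (102778162 to 102791738, minus strand, GRCm39), rose 2.29-fold. Its level was 274 ± 22.4 CPM in CCI and 119 ± 51.9 in control (SD, n = 3), a log2 fold change of 1.20 ± 0.31 (SE) with an adjusted p of 0.0115. All 3 CCI libraries lay above all 3 control libraries, and the gene passed in each of the 16 alternative settings, with log2 fold changes from 0.90 (without control replicate 6) to 1.89 (on log2(FPKM + 0.1)). Among 9 tested pan-reactive astrocyte genes, which rise in many forms of brain injury, 5 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. Vim, another intermediate filament gene, rose by 1.63 ± 0.33, the ceruloplasmin gene Cp by 1.20 ± 0.20 and the sphingosine phosphate receptor gene S1pr3 by 0.90 ± 0.22, while the low-count gene Steap4 fell (-2.40 ± 0.60). Cp was at 0.64 after correction for coding length and GC content and at 0.49 (adjusted p = 0.0594) with mean expression in the correction. Without CCI replicate 1 the S1pr3 change was 0.80 (adjusted p = 0.0513), and 3 members rose. The list as a whole did not pass the camera test (adjusted p = 0.308), but it passed by fry (adjusted p = 0.0279).

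General astrocyte markers did not move together. Of 18 tested, 3 rose, 8 fell and 7 did not pass, again with the same counts adjusted over the list alone (median -0.35, camera adjusted p = 0.101). With no filter the list passed as lower at the preset correlation (camera adjusted p = 0.0413), with the same counts. By fry it passed in the main fit (adjusted p = 0.0106). The gap junction gene Gjb6 fell from 434 ± 90.4 to 84.4 ± 19.9 CPM (-2.36 ± 0.24), the glycolytic enzyme gene Aldoc by 2.26 ± 0.28 and the neurotensin receptor gene Ntsr2 by 1.39 ± 0.20 on the log2 scale. The 3 that rose, named after their values were seen, were the water channel gene Aqp4 (0.87 ± 0.19), Mlc1 (0.72 ± 0.18) and Slc4a4 (0.52 ± 0.15). Slc4a4 was at 0.07 after correction for coding length and GC content. With mean expression in the correction Gjb6, Aldoc and Ntsr2 were at -1.34, -1.11 and -0.77, and each passed. The median of the list turned positive on log2(FPKM + 1), at 0.27 with 7 members higher and 3 lower. Corrected for coding length, GC content and mean expression it was 0.07, with 6 higher and 4 lower.

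Genes assigned to the A1 and A2 reactive astrocyte types were tested next. None of 12 tested A1-type genes rose and 2 fell, Fbln5 (-1.39 ± 0.25) and Amigo2 (-1.17 ± 0.21), while 1 of 8 A2-type genes rose, S100a10 (0.72 ± 0.15). These counts were the same adjusted over the list alone, and neither list passed (camera adjusted p = 0.536 and 0.650). On log2(FPKM + 1) Fbln5 was at -0.58 (adjusted p = 0.0525) and Amigo2 at -0.51 (adjusted p = 0.131), and 4 A1-type and 5 A2-type genes were higher. The A1-type median was -0.28, against 0.20 on log2(FPKM + 1) and 0.17 without control replicate 5.

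**Figure D1:**
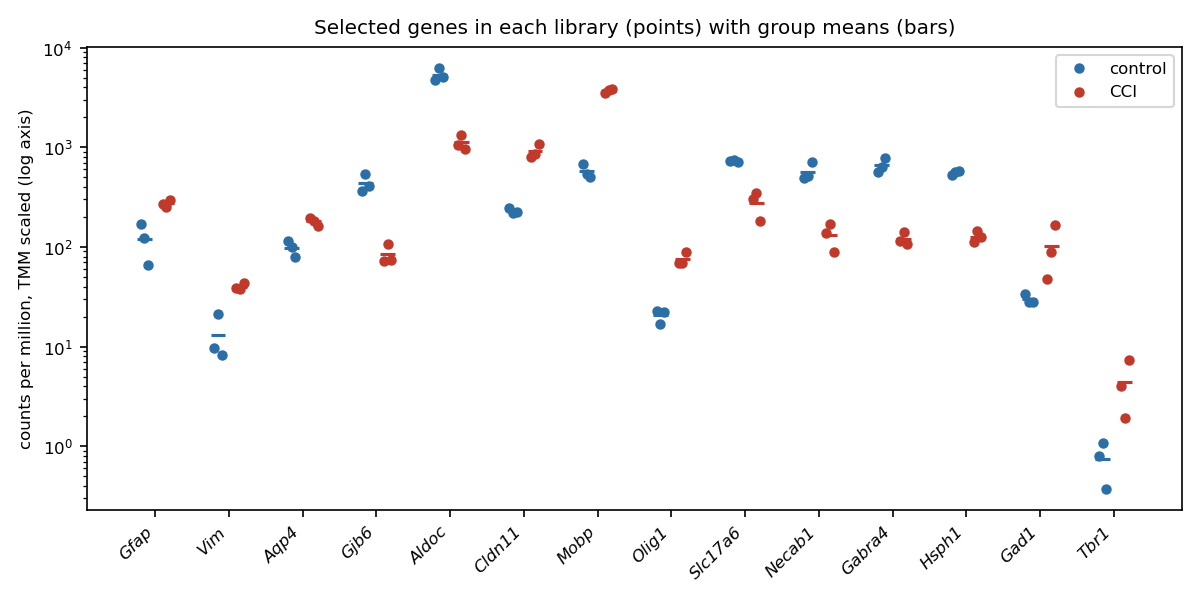
CPM after TMM scaling (vertical log axis) of 14 genes in the 3 control and 3 CCI libraries (points), with the mean of each group (short bars). Gfap, Vim, Aqp4, Cldn11, Mobp, Olig1, Gad1 and Tbr1 lay higher in CCI, and Gjb6, Aldoc, Slc17a6, Necab1, Gabra4 and Hsph1 lower.

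Among astrocyte receptors and calcium release genes, 6 of 19 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.536). Over all 14259 tested genes 3853 rose and 3608 fell, and on log2(FPKM + 1) 6785 were higher and 1374 lower. The counts of this and the other lists stand beside those shares. The ATP-gated channel gene P2rx7 rose by 2.04 ± 0.24 and the phospholipase gene Plcb1 by 1.15 ± 0.21, and the G protein gene Gnaq fell by 1.11 ± 0.18 (log2). The inositol trisphosphate receptor gene Itpr2 had a log2 fold change of 1.29 ± 0.19 and of 0.11 ± 0.20 after correction for coding length and GC content, where it no longer passed (adjusted p = 0.666) and 3 members of the list were higher and 4 lower. Lactate and glycogen genes went both ways, 3 of 15 higher and 7 lower (4 and 7 adjusted over the list alone), with the lactate dehydrogenase gene Ldhb falling by 1.18 ± 0.24 and the glycolysis regulator gene Pfkfb3 rising by 0.93 ± 0.22. With mean expression in the correction Ldhb was at -0.09 (adjusted p = 0.729) and Gnaq at -0.05 (adjusted p = 0.845). Astrocyte-secreted synaptogenic factors had 2 of 10 members higher and 4 lower, also adjusted over the list alone. Bdnf, a neuronal growth factor gene, fell by 0.95 ± 0.16 and the glypican gene Gpc6 rose by 1.17 ± 0.25. Neither list passed camera (adjusted p = 0.536 and 0.663). By fry the lactate and glycogen list passed (adjusted p = 0.0159) and the synaptogenic list did not (adjusted p = 0.157). On log2(FPKM + 1) the medians of these 3 lists were 0.25, 0.50 and 0.19, against -0.04, -0.05 and -0.02, with 9, 7 and 4 members higher and 0, 2 and 0 lower, and Gnaq (-0.50, adjusted p = 0.0555) and Bdnf (-0.32, adjusted p = 0.0973) did not pass, nor did Bdnf with mean expression in the correction (-0.39, adjusted p = 0.0723). Without control replicate 5, 6 receptor genes were higher and 5 lower. Without CCI replicate 1, 3 lactate and glycogen genes and 1 synaptogenic factor were lower, and without CCI replicate 3, 4 lactate and glycogen genes.

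Most oligodendrocyte genes rose, in the same libraries in which 9 of 14 hippocampal and cortical neuron genes rose and 8 of 15 thalamic genes fell. Of 18 myelin genes, 13 rose, none fell and 5 did not pass, with the same counts adjusted over the list alone (median 1.20). The camera test passed (adjusted p = 0.00188), but not with an estimated correlation between genes (adjusted p = 0.797 with an estimated correlation). Many lists share that adjusted value, and the unadjusted p of the myelin list in that test was 0.193. Mobp rose from 574 ± 95.2 to 3704 ± 184 CPM (2.69 ± 0.25), the myelin claudin gene Cldn11 by 1.98 ± 0.21, Mal by 1.42 ± 0.22 and Cnp by 1.23 ± 0.20. Mog (0.20 ± 0.23), a myelin gene picked after its values were seen, did not pass. Of 12 genes of the precursor list 7 rose, none fell and 5 did not pass, also adjusted over the list alone (median 1.11, camera adjusted p = 0.00525, adjusted p = 0.797 with an estimated correlation). Bcas1 rose by 2.36 ± 0.22, the transcription factor gene Olig1 by 1.87 ± 0.19, Vcan by 2.08 ± 0.23 and Enpp6 by 1.67 ± 0.21. Vcan was at 0.87 after correction for coding length and GC content and at 0.60 (adjusted p = 0.0434) with mean expression in the correction. Both lists passed the preset camera test without each library in turn, at adjusted p up to 0.0124, and after both trend corrections, at adjusted p up to 0.00416.

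Fewer than 0.5 of the members of each microglial and immune list passed. On log2(FPKM + 1), 11 microglia, 7 inflammatory and 15 interferon response genes were higher. Of 16 microglia markers 6 rose, 1 fell and 9 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.650), with the signalling adaptor gene Tyrobp rising by 0.81 ± 0.20. The number of higher markers was 1 without CCI replicate 3, 2 without CCI replicate 2 or control replicate 4, and 3 without CCI replicate 1 or control replicate 6. Of 11 inflammatory cytokine and sensor genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.450). The chemokine gene Ccl5 had 34 counts over the CCI libraries and 2 over the control libraries, a ratio of 16.6 with a 95% counting interval of 4.25 to 142, which covers counting error alone. Its log2 fold change was 3.81, and 3.16 without control replicate 6. The fractalkine gene Cx3cl1 fell by 1.79 ± 0.48, and without CCI replicate 1 its adjusted p was 0.0515, as against 0.229 on log2(FPKM + 1) (-0.91) and 0.0731 with mean expression in the correction (-1.04). Without control replicate 5, 5 inflammatory genes rose. Il1b, Tnf and Il6 had too few counts to be tested (9, 0 and 6 over all libraries). Of 19 interferon response genes 5 rose and 2 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.232), with the interferon signalling gene Stat2 rising by 1.36 ± 0.20 and Ifit2 falling by 1.26 ± 0.23. After correction for coding length and GC content the interferon list passed as higher, with 8 members higher and 1 lower (camera adjusted p = 0.0272), and uncorrected it had an adjusted p = 0.797 with an estimated correlation. With mean expression in the correction it did not pass (camera adjusted p = 0.192), with 4 members higher and 1 lower. Without control replicate 5, 11 interferon response genes rose, and without CCI replicate 2, 3 did.

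Markers of neuron types and neighbouring regions were compared list by list, with no test of one list against another. Of 15 paraventricular and midline thalamus genes none rose, 8 fell and 7 did not pass, with the same counts adjusted over the list alone (median -0.73, camera adjusted p = 0.0597). Necab1 fell from 569 ± 120 to 132 ± 41.9 CPM (-2.11 ± 0.28), the calretinin gene Calb2 by 1.58 ± 0.27, the vesicular glutamate transporter gene Slc17a6 by 1.41 ± 0.25 and the thalamic transcription factor gene Tcf7l2 by 1.99 ± 0.42. With mean expression in the correction Calb2 was at -0.52 (adjusted p = 0.136) and Slc17a6 at -0.64, and neither passed, nor did Gpr151 of the habenula list below (adjusted p = 0.0670). In 12 habenula genes none rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.171), including the orphan receptor gene Gpr151 (-1.79 ± 0.39). Of 14 hippocampal and cortical neuron genes 9 rose, none fell and 5 did not pass, also adjusted over the list alone (median 2.02). That list passed (camera adjusted p = 0.0401), but not with an estimated correlation (adjusted p = 0.797 with an estimated correlation). It did not pass by fry either (adjusted p = 0.0721). The transcription factor gene Prox1 rose by 1.05 ± 0.17 to 90.3 ± 14.3 CPM, C1ql2 by 2.21 ± 0.46, and the cortical transcription factor genes Fezf2 by 3.12 ± 0.65 and Tbr1 by 2.62 ± 0.59. Fezf2 and Tbr1 had low control levels, 0.347 ± 0.107 and 0.747 ± 0.348 CPM. Of 11 GABAergic neuron genes 7 rose and none fell, also adjusted over the list alone (median 1.77, camera adjusted p = 0.124), with the GABA-synthesising enzyme gene Gad1 rising from 29.8 ± 3.14 to 101 ± 60.4 CPM and Meis2 by 2.87 ± 0.52.

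The size of these regional differences varied between libraries. Without CCI replicate 3 the log2 fold changes of Fezf2, Tbr1 and Meis2 were 2.31, 2.02 and 2.18, against 3.12, 2.62 and 2.87 in all libraries, and 5 hippocampal and cortical genes (camera adjusted p = 0.0511), 4 GABAergic genes and 4 thalamic genes passed in the directions above. Without control replicate 5 the hippocampal and cortical list had an adjusted p of 0.0826, and without control replicate 6 it had 6 higher members. It did not pass on log2(FPKM + 1), at equal total counts or with mean expression in the correction (adjusted p = 0.205, 0.0548 and 0.0750). The thalamic list passed without CCI replicate 1, CCI replicate 2 or control replicate 6 (camera adjusted p = 0.0328, 0.0188 and 0.0348), with 5 members lower without CCI replicate 1, and after correction for coding length and GC content (adjusted p = 0.0400). It also passed as lower with no filter (adjusted p = 0.0375), with mean expression in the correction (0.0362) and on log2(FPKM + 1) (0.0208), where 2 of its members were higher and 4 lower. The habenula list passed as lower on that scale too (adjusted p = 0.0208), with 2 higher and 2 lower. With all libraries and no correction, the thalamic, GABAergic and habenula lists each had an adjusted p = 0.797 with an estimated correlation, and the passes given here are at the preset one. The GABAergic list passed without CCI replicate 1 (adjusted p = 0.00326) and after correction for coding length and GC content (adjusted p = 0.0278, 7 higher), and the habenula list without CCI replicate 1 or control replicate 6 (adjusted p = 0.0168 and 0.0199). With mean expression in the correction the GABAergic list did not pass (camera adjusted p = 0.0544, 6 higher). The habenula list had 1 member lower without CCI replicate 3, 2 without CCI replicate 2 and 4 without control replicate 4, and Gpr151 passed in each of those fits.

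Other neuronal lists were tested in the same way. Among 13 pan-neuronal markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.388), and the synaptic gene Snap25 fell from 5553 ± 1361 to 1472 ± 86.8 CPM (-1.92 ± 0.29). With mean expression in the correction Snap25 was at -0.61 (adjusted p = 0.0406). The microtubule gene Map2 had a log2 fold change of 0.65 ± 0.18, which was -0.21 (adjusted p = 0.318) after correction for coding length and GC content, and it did not pass without CCI replicate 1 or 2 or control replicate 4 or 6 (adjusted p from 0.0578 to 0.0785). Of 11 striatal genes 2 rose (0 adjusted over the list alone; camera adjusted p = 0.473) and of 6 tested hypothalamic genes 1 rose, Trh (0 adjusted over the list alone; camera adjusted p = 0.765). Trh did not pass without CCI replicate 1, CCI replicate 2, control replicate 4 or control replicate 6 (adjusted p from 0.0998 to 0.189) or with mean expression in the correction (adjusted p = 0.123), and the striatal gene Isl1 (1.65 ± 0.44) did not pass without CCI replicate 2 or 3 (adjusted p = 0.0506 and 0.0556). The pan-neuronal median was -0.25, and 0.34 on log2(FPKM + 1), and 5 pan-neuronal markers fell without control replicate 5. Of these markers 2 were higher and 1 lower on log2(FPKM + 1), and 4 and 1 with mean expression in the correction.

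Of 17 neuronal immediate early genes, whose transcripts rise with neuronal activity, 4 rose, 4 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.836). Arc rose by 2.25 ± 0.35 and Npas4 by 2.30 ± 0.40, Npas4 from a low control level of 0.540 ± 0.164 CPM. With mean expression in the correction Npas4 was at 0.98 (adjusted p = 0.102). Ier2 fell by 1.70 ± 0.25 and Dusp1 by 1.21 ± 0.19. Fos, picked after its values were seen, had a log2 fold change of 0.49 ± 0.27 (adjusted p = 0.151). On log2(FPKM + 1) 8 members were higher and 1 lower, and Dusp1 was at -0.59 (adjusted p = 0.0605). Without control replicate 5, 7 members rose.

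Receptor and channel genes were tested family by family, with no test of one family against another. Of 13 GABA-A receptor subunits 2 rose, 7 fell and 4 did not pass (2 and 8 adjusted over the list alone), with a median of -1.14. The list passed the camera test (adjusted p = 0.0181), but not with an estimated correlation (adjusted p = 0.797 with an estimated correlation). Gabra4 fell from 660 ± 112 to 121 ± 18.4 CPM (-2.45 ± 0.22) and Gabra3 by 2.04 ± 0.22. The 2 that rose, named after their values were seen, were Gabra2 (0.99 ± 0.16) and Gabrb1 (0.90 ± 0.16). The list stayed lower on log2(FPKM + 1), with 6 members lower and 4 higher, and did not pass after correction that included mean expression (adjusted p = 0.134) or with the stricter filter (adjusted p = 0.130). These falls stood beside the fall of thalamic markers and the rise of Gad1 in the same libraries.

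Excitability channels linked to pain, had 11 of 20 members higher, none lower and 9 not past, also adjusted over the list alone (median 0.55, camera adjusted p = 0.0107, adjusted p = 0.797 with an estimated correlation). Cacna2d2 rose by 1.71 ± 0.19 and Cacna1a by 2.02 ± 0.23. These are long genes, with a median coding length of 4722 bp, and after correction for coding length and GC content 2 members were higher and 4 lower (median -0.11, camera adjusted p = 0.889), and with the stricter filter the adjusted p was 0.102. After that correction Cacna2d2 still passed (0.76, adjusted p = 0.0145), and Cacna1a did not (0.46, adjusted p = 0.0872). Among 17 ionotropic glutamate receptors 11 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0597), and 3 rose and 3 fell after that correction. Gria4 rose by 1.77 ± 0.26 and the NMDA receptor gene Grin2a fell by 2.22 ± 0.37, and both passed after it. The glutamate receptor list passed without CCI replicate 1, CCI replicate 2 or control replicate 6 (adjusted p = 0.0392, 0.0394 and 0.0348), with 8, 9 and 9 members higher, and 7 were higher without CCI replicate 3 or control replicate 4. With all libraries it had an adjusted p = 0.797 with an estimated correlation.

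In the opioid list, 1 of 7 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.818). The mu receptor gene Oprm1 rose from 13.7 ± 4.80 to 36.4 ± 8.72 CPM (1.40 ± 0.30), and the nociceptin receptor gene Oprl1 fell by 1.20 ± 0.19. Of 20 monoamine and neuropeptide receptors 1 rose and 6 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.450), with the serotonin receptor gene Htr7 falling by 1.11 ± 0.17 and the urocortin receptor gene Crhr2 rising by 2.45 ± 0.53. Crhr2 had a low control level of 0.457 ± 0.343 CPM. On log2(FPKM + 1), Oprl1 (-0.54, adjusted p = 0.0962) and Htr7 (-0.45, adjusted p = 0.0533) did not pass and no monoamine or neuropeptide receptor was lower. The medians of the opioid and receptor lists were -0.05 and -0.29, and 0.35 and 0.16 on that scale, with 3 and 4 members higher and 0 lower in either. Without CCI replicate 1 or 2, 3 of these receptors were lower.

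Several heat shock genes and nuclear genes of oxidative phosphorylation fell in CCI. None of 12 heat shock genes rose, 7 fell and 5 did not pass, also adjusted over the list alone (median -0.81, camera adjusted p = 0.0195, adjusted p = 0.797 with an estimated correlation). Hsph1 fell from 555 ± 23.5 to 126 ± 16.5 CPM (-2.13 ± 0.19), Dnaja1 by 1.66 ± 0.23 and Hspa8 by 1.59 ± 0.29. Of 30 nuclear genes of oxidative phosphorylation 1 rose, 14 fell and 15 did not pass (0 and 9 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.0200, adjusted p = 0.797 with an estimated correlation). Ndufa7 fell by 1.51 ± 0.30 and Ndufa1 by 1.26 ± 0.25. That list had 5 members lower without CCI replicate 1, 6 without CCI replicate 2, 8 without CCI replicate 3 and 21 without control replicate 4, and did not pass without control replicate 5 (adjusted p = 0.111). It did not pass with the stricter filter (adjusted p = 0.385), after correction for coding length and GC content (adjusted p = 0.115) or after correction that included mean expression, where its direction turned (8 higher, 0 lower, adjusted p = 0.229), and it passed as lower on log2(FPKM + 1) and log2(FPKM + 0.1) (adjusted p = 0.0208 and 0.0228), with a median of 0.02 on each, 5 members higher and 4 lower. The heat shock list did not pass with the stricter filter or with mean expression in the correction (adjusted p = 0.102 and 0.267), and on log2(FPKM + 1) it had 2 members higher and 3 lower (median -0.20). With mean expression in the correction Ndufa7 was at -0.66 (adjusted p = 0.0580) and Ndufa1 at -0.24 (adjusted p = 0.209). In that fit Hsph1, Dnaja1 and Hspa8 were at -1.69, -0.67 and -0.80, and each passed.

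Of 41 cytosolic ribosomal protein genes 19 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0597). Rpl11 rose by 1.29 ± 0.16 and Rps23 by 1.22 ± 0.17, and after correction for coding length and GC content 22 rose and 2 fell (camera adjusted p = 3.15e-06). Without the correction the list had an adjusted p = 0.797 with an estimated correlation. Reads of these genes can be shared with near-identical pseudogenes. At the preset correlation the list passed without CCI replicate 1 or control replicate 5 (adjusted p = 0.0386 and 0.00542), and did not without control replicate 4 (adjusted p = 0.229). It also passed with the stricter filter (26 higher, 2 lower, adjusted p = 0.000352) and with mean expression in the correction (28 higher, 0 lower, adjusted p = 6.08e-15). Mitochondrially encoded genes had 3 of 11 members higher and none lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.536), with mt-Nd4 rising by 1.42 ± 0.28. Genes of the mitochondrial genome took 1.77% ± 0.12 of the counts in CCI and 0.888% ± 0.337 in control (SD, n = 3), and without control replicate 5, 7 of the 11 rose and the list passed (adjusted p = 0.0172). With all libraries it had an adjusted p = 0.870 with an estimated correlation. Without CCI replicate 3, control replicate 4 or control replicate 6, 1 of the 11 rose.

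Other cell types gave mixed results, and none of their lists passed. Of 16 choroid plexus genes 3 rose and 1 fell, of 13 ependymal genes 3 rose, of 13 endothelial genes 3 rose and 2 fell, of 10 mural genes 3 rose and 3 fell, of 13 meningeal fibroblast genes 3 rose and 1 fell, and of 7 red blood cell genes 3 rose and 2 fell, all with the same counts adjusted over the list alone (camera adjusted p = 0.663, 0.249, 0.650, 0.980, 0.13 and 0.667). Itm2a, an endothelial marker, fell by 2.67 ± 0.28, the pericyte gene Pdgfrb rose by 1.91 ± 0.29, and the haemoglobin gene Hbb-bt, whose reads can be shared with its paralog, rose by 2.48 ± 0.28. The haemoglobin gene Hbb-bs also rose (0.99 ± 0.22), while Fech of the red blood cell list fell (-1.87 ± 0.25). The blood content of the tissue was not tested. The ciliary genes Dnah11 and Foxj1 rose by 2.63 ± 0.28 and 1.44 ± 0.36. Corrected for coding length and GC content Dnah11 was at 1.22 and Pdgfrb at 1.07, and with mean expression also corrected at 0.79 and 0.96. The endothelial and mural medians were -0.23 and -0.05, and 0.25 and 0.21 on log2(FPKM + 1), where 4 mural genes were higher and 0 lower. With mean expression in the correction 3 meningeal genes were higher and 3 lower. After correction for coding length and GC content 0 endothelial genes were higher and 5 lower, and 1 mural gene was higher and 4 lower. Without control replicate 5, 9 ependymal, 8 meningeal and 5 red blood cell genes rose, and without control replicate 4, 5 meningeal genes. Without control replicate 6, 4 choroid plexus genes fell. The endothelial list had 1 member higher without CCI replicate 1, 2 or 3 or control replicate 6, and the mural list 1 without CCI replicate 1.

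Among 15 glucocorticoid-responsive genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.248). Hif3a rose by 2.25 ± 0.41 and the kinase gene Sgk1 by 1.51 ± 0.38, whereas Tsc22d3 was at -1.26 ± 0.27, or -0.80 (adjusted p = 0.0624) after correction for coding length and GC content and -0.65 (adjusted p = 0.101) on log2(FPKM + 1). The list passed without CCI replicate 1 (adjusted p = 0.0361; with all libraries adjusted p = 0.797 with an estimated correlation), and 4 members were higher without CCI replicate 3. Of 15 circadian clock genes 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.765). Clock rose by 1.18 ± 0.14 and Tef by 1.06 ± 0.15, and Ciart had a log2 fold change of -1.05 ± 0.16, or -0.42 (adjusted p = 0.0569) on log2(FPKM + 1). The number of lower clock genes was 1 without CCI replicate 1, 2 without CCI replicate 2 or 3, and 3 without control replicate 4 or 6. The median of the clock genes was -0.04, and 0.52 on log2(FPKM + 1), where 8 were higher and 0 lower. After correction for coding length and GC content 2 were higher and 5 lower, and with the stricter filter 5 and 1.

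Of the 37 lists, 7 passed the camera test at its preset correlation, 4 higher and 3 lower. None of the 7 passed with an estimated correlation, 0 of 37 in all. Their unadjusted p there ran from 0.0495 (excitability channels) to 0.546 (oxidative phosphorylation), and adjustment gave each the same 0.797. By fry 12 lists passed. Of the 7, hippocampal and cortical neurons (adjusted p = 0.0721) and oxidative phosphorylation (adjusted p = 0.160) did not. The others past by fry were astrocyte markers, pan-reactive astrocyte, lactate and glycogen, inflammatory, pan-neuronal, thalamic and glutamate receptor genes.

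**Figure D2:**
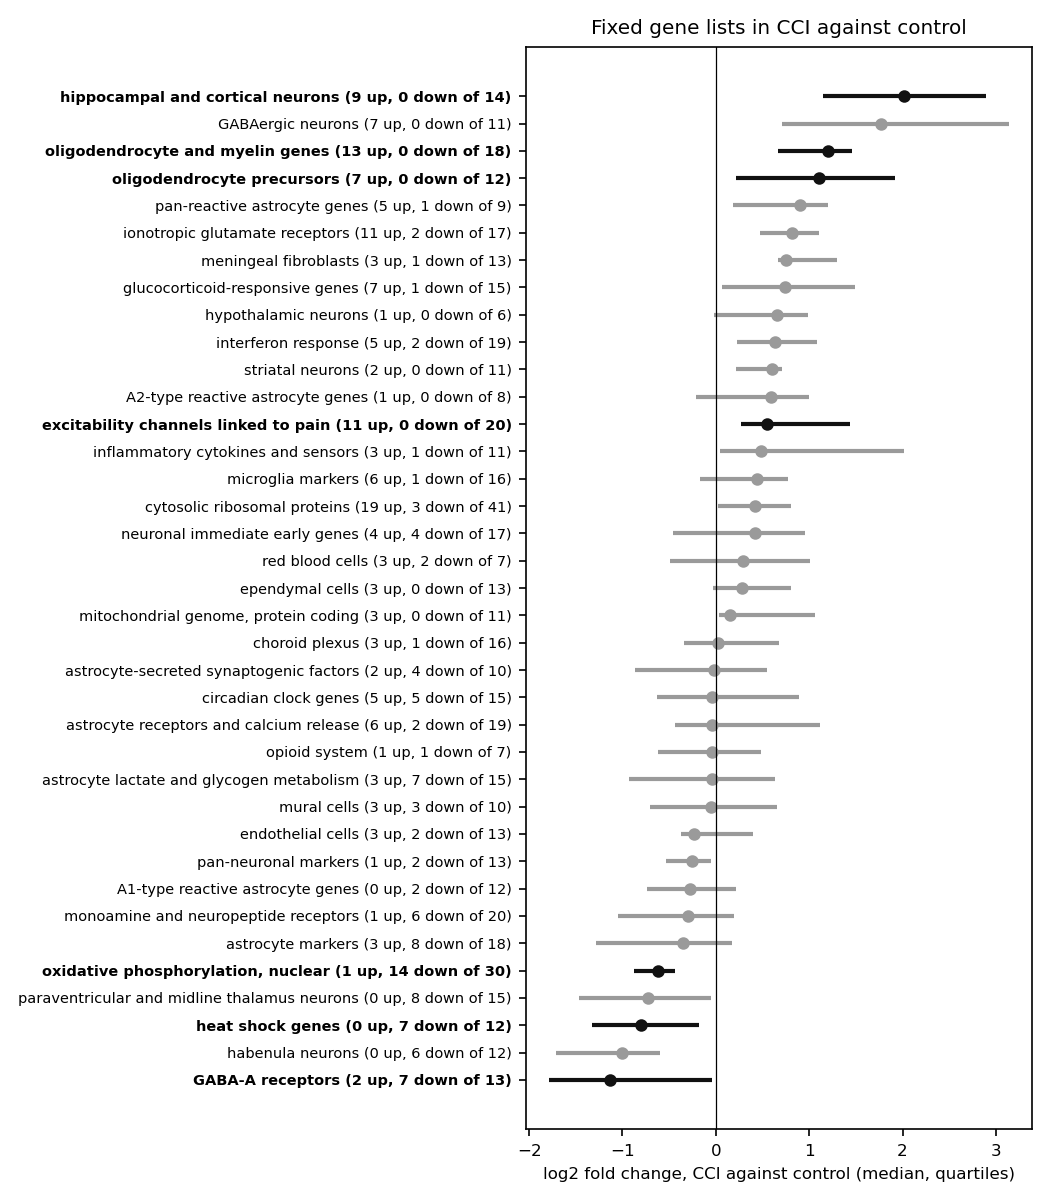
Median log2 fold change (points) and quartiles (bars) of the tested members of each of 37 gene lists in CCI against control, with the numbers of members past the threshold in brackets. The 7 lists past the camera test at its preset correlation are in black; hippocampal and cortical neurons had the highest median (2.02) and GABA-A receptors the lowest (-1.14).

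The largest changes that met the naming rule were mostly in genes with few counts in one group. The 10 largest rises were Tas2r125, Lhx1, Dlx1, Klhl34, Slc26a10, Semp2l1, Igfbpl1, Sytl5, Olfr1507 and Dthd1, with log2 fold changes from 3.88 to 5.07 and 2 to 16 counts over the 3 control libraries. Lhx1 (ENSMUSG00000018698, chromosome 11, 84409110 to 84416361), a developmental transcription factor gene, rose from 0.268 ± 0.0314 to 6.91 ± 2.45 CPM (4.61 ± 0.46, adjusted p = 0.000228). Semp2l1 (chromosome 1, 32582767 to 32586375) rose from 0.238 ± 0.0604 to 4.31 ± 0.273 (4.10 ± 0.39). The bitter taste receptor gene Tas2r125 had 80 counts in CCI and 2 in control, a ratio of 39.0 with a 95% counting interval of 10.4 to 327, and Klhl34 had 66 and 3, a ratio of 21.4 with an interval of 7.02 to 107. Tas2r125 and Olfr1507 belong to large receptor families, so their counts are uncertain. Dlx1 and Igfbpl1 were highest in CCI replicate 3, at 14.2 and 10.4 CPM, and without it their log2 fold changes were 2.29 and 2.65 against 4.33 and 4.08. Dlx1 did not pass on log2(FPKM + 1) (0.90, adjusted p = 0.0963). The control counts of Sytl5 (6) and Tas2r125 (2) all came from replicate 4, so no fold change is given for them without it. Without that replicate the log2 fold changes of Klhl34, Slc26a10, Olfr1507 and Dthd1 were 5.03, 5.22, 4.68 and 4.64, against 4.22, 4.17, 3.95 and 3.88. Without control replicate 6 those of Tas2r125, Klhl34, Sytl5 and Olfr1507 were 4.42, 3.56, 3.29 and 3.27, against 5.07, 4.22, 3.97 and 3.95, and each of these genes passed in both fits.

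The largest falls included Mael, Krt1, Rab5if, Fbp2, Opn3, Trim40, AI593442, Tspan12 and Fnta, with log2 fold changes from -4.56 to -3.39. AI593442 was the most abundant of them, falling from 5988 ± 3424 to 519 ± 181 CPM (-3.53 ± 0.48). Tspan12, which encodes a tetraspanin of Norrin signalling, fell from 598 ± 345 to 56.3 ± 11.2 (-3.41 ± 0.40), and Fnta (chromosome 8, 26488750 to 26505678), the alpha subunit gene of protein farnesyltransferase, from 585 ± 115 to 55.7 ± 12.6 (-3.39 ± 0.25). AI593442 and Tspan12 were highest in control replicate 5, at 9902 and 996 CPM. They were at 3549 and 384 in control replicate 4 and at 4514 and 412 in control replicate 6. Opn3 (chromosome 1, 175489987 to 175520342), an extraocular opsin gene, fell from 45 ± 11.8 to 3.56 ± 0.309 (-3.66 ± 0.25), and Krt1 (chromosome 15, 101753861 to 101759229), a keratin gene, from 9.61 ± 1.35 to 0.499 ± 0.0415 (-4.23 ± 0.31). Mael had 6 counts over the CCI libraries and 136 over the control libraries, and its log2 fold change was -6.20 without CCI replicate 3 and -3.96 without control replicate 5, while that of Fbp2 was -5.01 without CCI replicate 1.

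Fold changes followed coding length and abundance. Across 14220 genes, which are not independent replicates, Spearman's correlation of the log2 fold change was 0.39 with coding length, 0.17 with GC content and -0.44 with mean expression. Each CCI library lay on one side of the length trend (correlations with coding length of 0.35 to 0.39) and each control library on the other (-0.30 to -0.35). With the trends of each library on coding length and GC content removed, 6515 genes passed, 2816 higher and 3699 lower. Of these, 5202 had passed before in the same direction and 57 in the opposite one. This correction left the correlation with mean expression at -0.41. With that trend removed as well 5546 genes passed, 4163 of them in the same direction as before and 34 in the opposite one.

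**Figure D3:**
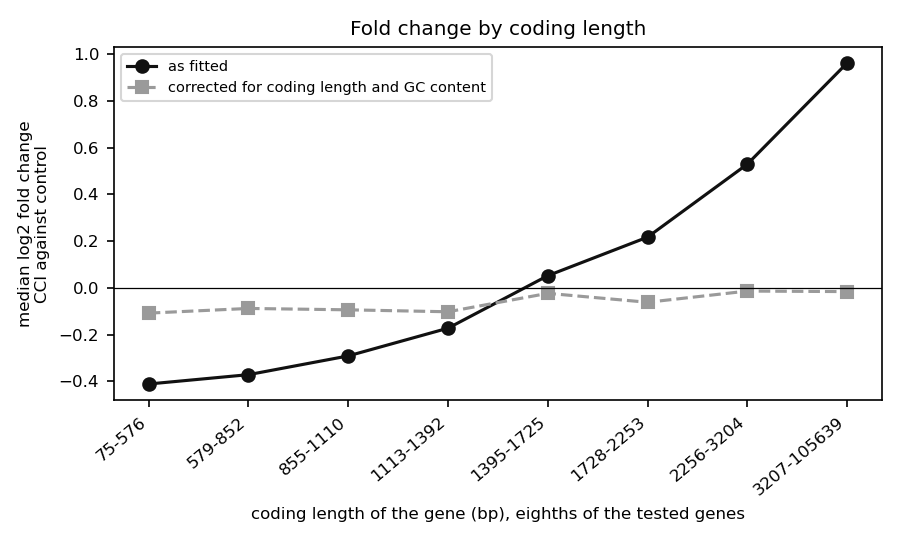
Median log2 fold change of CCI against control (vertical axis) over eighths of the tested genes ordered by coding length in bp (horizontal axis), as fitted (circles) and corrected for coding length and GC content (squares). The fitted medians ran from -0.41 in the shortest genes to 0.96 in the longest, and the corrected ones lay between -0.11 and -0.01.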

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

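No paired analysis was possible because the groups share no replicate numbers (1 to 3 against 4 to 6). The trend corrections and the thinning to equal total counts were chosen after the data were seen. Against 7461 genes (3853 higher, 3608 lower), the stricter filter, which tests fewer genes, gave 4017 (2115 higher, 1902 lower). Unadjusted p under 0.05 with over 2-fold gave 4767 (2072 lower). Limma on log2(FPKM + 1) gave 6785 higher and 1374 lower, and on log2(FPKM + 0.1) 6632 and 1345, where the total-count scale moves all genes up. Leaving out 1 library gave 5474 to 8904 genes and 6 to 13 lists, against 7. The stricter filter gave 3 lists, fry 12 and an estimated correlation 0. Gfap passed in all 16 settings (0.90 to 1.89). Corrected for coding length and GC content, excitability channels turned (adjusted p = 0.889), as did Map2 (-0.21), Adcy5 (-0.74), Flt1 (-0.17), Kdr (-0.0398), Abcc9 (-0.00881) and Cacna1i (-0.22). With mean expression also corrected, oxidative phosphorylation turned (adjusted p = 0.229), as did Itpr2 (-0.0148), Nefl (0.18), Kdr (-0.20), Abcc9 (-0.23) and Cacna1i (-0.20). Slco1a4 was at 0.0624 on log2(FPKM + 1) and 0.0689 on log2(FPKM + 0.1). Beyond what the filter and scale do by construction, the cause was not tested. In simulated data at this depth, with 200 of 14220 genes changed, 37% of 2-fold and 88% of 4-fold changes were recovered. In the data 52.3% of the genes passed, so these rates do not give the power of the test here.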

Other observations

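Among terms with more genes lower than higher in CCI were several of protein turnover and mitochondria. Of 2067 Gene Ontology terms of the deposited annotation with 15 to 300 tested genes, 90 passed camera at its preset correlation, 33 higher and 57 lower. None passed with an estimated correlation (adjusted p = 0.844 for mitochondrial translation), and 77 passed without control replicate 5. In mitochondrial translation 2 of 90 genes rose and 58 fell (median -0.83), in the proteasome accessory complex none of 17 rose and 15 fell (-1.42), in the membrane of COPI-coated vesicles, which carry proteins back to the endoplasmic reticulum, none of 16 rose and 14 fell (-1.21), and in the tricarboxylic acid cycle 2 of 31 rose and 20 fell (-1.11). These and 2 more falling terms were the 6 that also passed after correction for coding length and GC content, and 0 passed with mean expression in the correction as well, where the respirasome and complex I assembly terms turned higher (adjusted p = 0.941 and 0.958). On log2(FPKM + 1) the medians of the 4 named terms were -0.20, -0.69, -0.51 and -0.49. Unlike the myelin list, the myelin sheath term passed as lower, with 30 of 180 genes higher and 84 lower (median -0.43, camera adjusted p = 0.0292). It did not pass after correction for coding length and GC content (adjusted p = 0.111), and its median on log2(FPKM + 1) was 0.19.

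Some terms had more genes higher than lower. In cilium movement 23 of 51 genes rose and 1 fell, in the collagen trimer 28 of 53 rose and 2 fell, and in semaphorin and plexin signalling, which guides axons, 24 of 36 rose and 4 fell. These terms did not pass after correction for coding length and GC content (adjusted p = 0.186, 0.406 and 0.824) or with an estimated correlation (adjusted p = 0.859, 0.844 and 0.844).

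Of the tests below, the one on the share of astrocytes was written after its values were seen, and the trend correction and the thinning to equal total counts were not among the settings planned before the data were examined.

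Of the tested genes 52.3% passed between CCI and control. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave this many genes, the real one with 7461, the highest other gave 0, and the share cannot go under 0.05 with 10 splits, so this test alone cannot tell whether the grouping arose by chance. With trends on coding length and GC content removed 6515 genes passed, 5202 of them in the same direction as in the main fit. With the total counts of the libraries matched 7305 passed. So neither those trends nor the difference in total counts accounts for most of the calls. The stronger trend on mean expression (-0.44) was not part of this test. With it removed as well 5546 genes passed, 4163 of them in the same direction as in the main fit. Matching totals left effective depth unequal, as TMM factors ran from 0.69 to 1.25. The labels name no preparation batch, and a difference in tissue handling or library preparation between the groups could produce such a count as well as the injury could. The controls were untreated, with no sham-operated group. Effects of surgery itself therefore cannot be told apart from those of the nerve injury.

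In CCI 9 of 14 cortical and hippocampal and 7 of 11 GABAergic genes were higher and 8 of 15 thalamic genes lower. Of these lists the first alone passed camera at the preset correlation (adjusted p = 0.0401, or 0.797 with an estimated correlation). By fry the thalamic list alone passed (adjusted p = 0.0383). In a second set of telencephalic genes, none of them in a fixed list, the median after correction for coding length and GC content was 0.719 (5 of 24 higher, 2 lower). In that fit 2816 of all 14220 genes were higher, a similar share, and the least abundant eighth of genes had a median of 0.56. With mean expression corrected the telencephalic median was 0.52 (4 higher, 2 lower). In a second thalamic set the median after the first correction was -1.08 (13 of 18 lower). It was -0.55 (8 lower) with mean expression corrected, -0.43 (6 of 16) with the stricter filter and -0.17 (5 lower, 1 higher) on log2(FPKM + 1). The signs of these medians would follow from more telencephalic tissue and less thalamus in the CCI libraries, but the telencephalic counts add little to this. Of the neighbours, 0 of 12 habenula genes rose and 6 fell, and the 6 of 15 hypothalamic genes that could be tested had a median of 0.66 with 1 higher, which leaves that region open. Without CCI replicate 3 the uncorrected telencephalic median was 0.47 against 0.78, and the myelin rise in the same libraries (13 of 18) was not tested against tissue content. Of the 9 hippocampal and cortical genes that rose, 7 still passed as higher after correction for coding length and GC content, so the length trend does not explain those 7. With mean expression corrected as well, 6 members of the list were higher and it did not pass (camera adjusted p = 0.0750).

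Gfap and other pan-reactive astrocyte genes were higher in CCI. A larger share of astrocytes alone would raise astrocyte markers by about as much as Gfap (1.20). In the main fit their median was -0.35 with 3 higher and 8 lower and the highest at 0.87. The members went both ways, and the median was 0.27 on log2(FPKM + 1) (7 higher, 3 lower), 0.07 with mean expression corrected (6 and 4) and 0.01 with the stricter filter (5 and 7). The criterion, that the median not be positive and more markers fall than rise, was written after its values were seen. It held in the main fit but not in these settings, so it cannot decide on the share of astrocytes. A larger share alone does not account for the members that fell. Corrected for coding length and GC content Gfap was at 1.08, so the length trend does not explain its rise. The rise may reflect reactive astrocytes, a larger share of astrocytes, or the possible difference in tissue content described above, which was not tested for this gene.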
